A study of Caenorhabditis elegans with 12 samples.

How the data were processed

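The series holds 12 Affymetrix C. elegans arrays in 4 groups of 3: cells carrying a GFP reporter driven by the mir-124 promoter (GFP+) and cells without it (GFP-), each from wild-type and from mir-124 mutant embryos. Per the labels' protocols, embryos were dissociated, the cells were cultured for 24 hours and sorted by flow cytometry into samples of 500000 cells, and the small amount of RNA was amplified before labelling. The series design describes the triplicates as biological; whether each came from its own culture or sorting day is not given in the sources used here, so p-values measure the spread between these samples.

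The deposited values are log2 expression summaries, 1 per probe set and array. The submitters' processing notes name RMA, MAS5, affy and limma, without versions or roles; RMA makes background-corrected, quantile-normalized log2 values, and MAS5 makes linear ones; which of them made the deposited table is not settled here. The array medians lay between 5.391 and 5.509 on the log2 scale, and no further scaling was applied. With array medians this close, a shift common to all transcripts of a sample could not be seen. Scanner files and the signal over local background were not used here; the number of arrays limits the precision, and depth in the sense of read counts does not apply.

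The table had 22625 probe sets, of which 77 controls were set aside and 22548 were tested. The platform annotation gave 20766 of them a single gene, 887 several genes and 895 no gene. Gene symbols were looked up by gene identifier in the RefSeq annotation of WBcel235, which changed 0 symbols; positions in it were used only to find the gene whose span holds mir-124 and the gene order around it. Each of 17118 genes was represented by the single-gene probe set with the highest mean over the 12 arrays. Probe sets whose names end in _s_at or _x_at can bind transcripts of related genes, and this is marked in the text for the genes called between the strains.

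Tests used limma 3.58.1 in R 4.3.3: lmFit with a mean for each of the 4 groups over all 12 arrays, eBayes, 2-sided, and Benjamini-Hochberg adjustment over the 22548 probe sets, with an adjusted p of 0.05 as the threshold. The contrasts were GFP+ minus GFP- in wild-type and in mutant, mutant minus wild-type in GFP+ and in GFP-, and the difference between the last 2 (the interaction). Gene lists were tested with limma's camera on representative probe sets with a preset inter-gene correlation of 0.01, adjusted over the 23 lists of a contrast, and again with an estimated correlation. The lists covered cilium and intraflagellar transport, sensory signalling, guanylyl cyclases, chemoreceptor families, pan-neuronal genes, neuropeptides, dopamine and serotonin neurons, motor neurons, touch receptor neurons, glia, body wall muscle, pharynx, intestine, hypodermis, collagens, germline, coelomocytes, cell cycle, ribosomal proteins, oxidative phosphorylation, proteasome, heat shock and stress, and the microRNA pathway. Figures were drawn with matplotlib 3.10.9.

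Named genes followed a fixed rule among genes past the threshold. The 10 largest rises and falls were taken for GFP+ against GFP- in wild-type and for mutant against wild-type in GFP+. For the other contrasts the 5 largest of each were taken. Replicate ranges of these genes could not overlap between the groups, except in the interaction. Up to 3 rises and 3 falls per list were added without the range condition, and trpa-1, lin-15A and lin-15B whatever their p. The groups, tests, lists, this rule and most alternatives were fixed before the data were examined. Of the genes named whatever their p, lin-15A and lin-15B are given only for mutant against wild-type in GFP+. A planned test of miR-124 seed sites in 3' UTRs was not run, since no UTR or genome sequence was used here.

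Both wild-type replicate 3 arrays stood apart in most measures of their control probe sets, and the library labelled wild-type GFP- replicate 3 had a GFP+ profile (given in the report). A fit without this pair, called the 10-array fit, was added after seeing the data and is reported beside the 12-array results. Same-numbered arrays of the GFP+ and GFP- groups deviated together from their group means in wild-type (correlations across probe sets of 0.485, 0.41 and 0.418) and in mutant (0.36, 0.435 and 0.359). So did the mutant and wild-type GFP+ arrays (0.278, 0.185 and 0.229). The GFP- arrays of the 2 strains did not (0.232, -0.0696 and -0.0294). Replicate numbers were therefore read as pairing the groups that deviated together, but the main fits did not block on them. Both wild-type replicate 3 arrays stood apart in the same way, which can raise the 3 wild-type correlations of GFP+ with GFP- together. The correlations were not computed without that pair. Fits with the replicate number as a block were alternatives, next to another normalization, an array-median shift, array weights, a filter on the dimmest 25% of probe sets, trended and robust eBayes, fits on the compared groups alone, and each array left out in turn.

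The test was tried on simulated data with the residual spread of the real arrays and 200 changed probe sets among 22548. For the mutant GFP+ against GFP- contrast with 12 arrays, 35.8% of changes of 1 log2 unit and 66.7% of changes of 2 units were recovered, with 2 false calls. For mutant against wild-type in GFP+ the shares were 41.8% and 72.7%, with 7 false calls. For the interaction they were 13.4% and 48.5%. The simulated errors were independent between arrays and few probe sets changed. The shares therefore need not hold for the real GFP+ against GFP- contrasts, where many more passed and same-numbered arrays deviated together.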

Results

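The arrays measured transcript levels in sorted embryonic C. elegans cells, to ask which transcripts mark cells in which the promoter of the microRNA gene mir-124 is active and which transcripts change when the microRNA is lost. There were 3 arrays each of wild-type GFP+, wild-type GFP-, mutant GFP+ and mutant GFP- cells. No probe set on the array is annotated to mir-124, so the mutation could not be read from its own product. On the WBcel235 annotation mir-124 lies within the span of trpa-1, which encodes a TRPA-type ion channel. Its tests are given for the contrasts between the strains and for the interaction. Between the fractions, its log2 signal was 9.4 to 9.697 in mutant GFP+ and 7.786 to 8.072 in mutant GFP- cells. In wild-type it was 6.861 to 7.778 in GFP+ and 5.419 to 7.089 in GFP- cells.

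Cilium and muscle genes separated the GFP+ from the GFP- libraries, with 1 exception. The mean log2 signal over 57 cilium genes was 7.934 to 8.471 in 5 GFP+ arrays and 5.498 to 5.726 in 5 GFP- arrays, and the mean over 58 body wall muscle genes was 7.409 to 7.645 and 8.813 to 9.41 in the same arrays. The library labelled wild-type GFP- replicate 3 had a cilium mean of 8.681 and a muscle mean of 7.522, next to 8.637 and 7.444 in wild-type GFP+ replicate 3. It correlated with that array at r = 0.977 across probe sets and with the other wild-type GFP- arrays at 0.893 to 0.903, while within-group correlations among the other 10 arrays were 0.968 to 0.991. Both wild-type replicate 3 arrays also had the widest signal gap between 3' and middle probe sets of the polyadenylated control RNAs, 4.221 and 4.061 log2 units against 1.665 to 2.313 in the other 10 arrays.

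**Figure D1:**
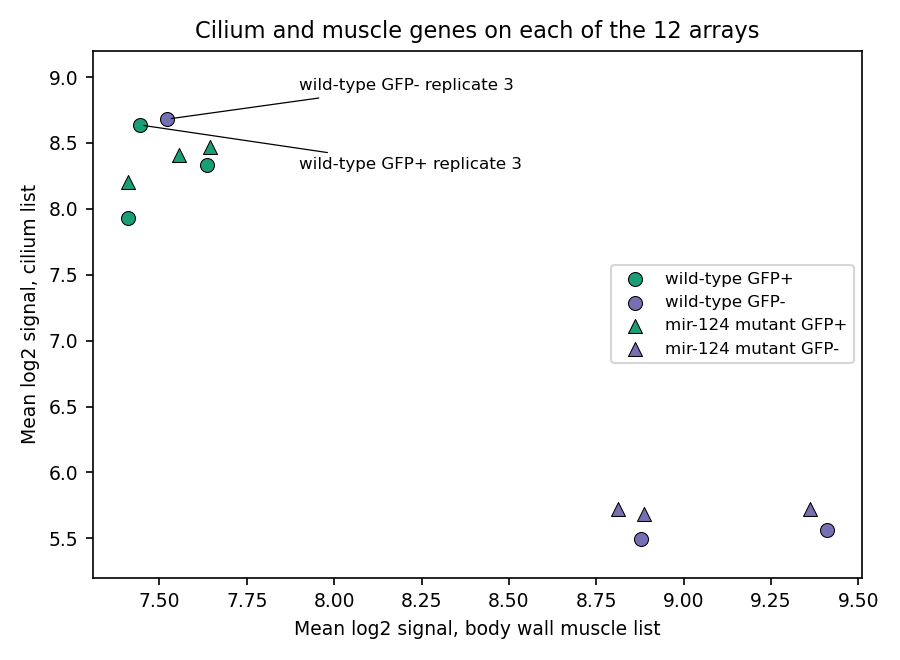
Mean log2 signal of the body wall muscle list (x axis) and of the cilium list (y axis) on each of the 12 arrays, 1 point per array, with colour for GFP status and shape for strain. The library labelled wild-type GFP- replicate 3 sits at 8.681 on the cilium axis, among the GFP+ arrays, while the other 5 GFP- arrays lie at 5.498 to 5.726.

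GFP+ against GFP- in the mir-124 mutant asked which genes mark the mir-124 promoter-active cells. These 6 arrays do not include the pair above, so the fold changes do not rest on it. The standard errors and the calls do rest in part on the pair, since the fit shares its residual spread over all arrays. The count without the pair is given further below. Genes of cilia and sensory neurons were higher in GFP+ cells and genes of muscle, cuticle and gut were lower. The largest rises were R102.2 (log2 fold change 6.56 ± 1.61, SE), F10E9.1 (5.95 ± 1.25), xbx-9 (5.91 ± 1.29), Y41E3.5 (5.70 ± 1.43) and xbx-3 (5.27 ± 1.11), the xbx genes being named for the X-box promoter motif of ciliary genes. The largest falls were asp-5 (-5.56 ± 0.782), an aspartyl protease, upb-1 (-4.93 ± 0.716), cpi-1 (-4.79 ± 0.742), a cystatin, spp-10 (-4.72 ± 0.719), a saposin, and F35C12.3 (-4.64 ± 0.803). With limma, 2730 probe sets passed an adjusted p of 0.05, 1309 higher and 1421 lower, for 1089 and 1130 genes.

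Among neuronal lists, 34 of 57 cilium genes rose in mutant GFP+ cells and 0 fell (54 and 0 adjusted over the list alone), with a list median of 2.91. Examples are che-11 (4.87 ± 1.31) and dyf-13 (4.34 ± 0.988) of intraflagellar transport and tmem-231 (4.31 ± 1.09) of the transition zone. Of 46 sensory signalling genes 18 rose (29 rose and 2 fell adjusted over the list alone). Among them were daf-11 (4.95 ± 1), a receptor guanylyl cyclase, daf-7 (4.50 ± 0.809), a TGF-beta ligand, and tax-4 (3.42 ± 0.743), a cyclic-nucleotide-gated channel subunit. Of 32 guanylyl cyclases 15 rose (21 adjusted over the list alone). These included gcy-33 (4.15 ± 1.07) and gcy-32 (3.14 ± 0.423), both soluble cyclases, and gcy-23 (3.04 ± 0.513). Camera called these 3 lists (adjusted p = 3.19e-22, 2.85e-11 and 2.48e-11), but adjusted p = 0.258, 0.252 and 0.252 with an estimated correlation. Of 1272 chemoreceptor genes 105 rose and 2 fell (59 and 0 adjusted over the list alone), led by srsx-3 (3.83 ± 0.69) and sru-13 (3.77 ± 0.934). The list median was 0.17 (camera adjusted p = 2.84e-10; adjusted p = 0.261 with an estimated correlation).

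General neuronal genes were higher as well. Of 43 pan-neuronal genes 27 rose in mutant GFP+ cells (33 adjusted over the list alone). These included aex-3 (2.58 ± 0.471), rab-3 (2.36 ± 0.31), a synaptic vesicle GTPase, and rbf-1 (2.25 ± 0.446), a rabphilin. Of the neuropeptide genes 24 rose, 3 fell and 81 did not pass (32 rose and 8 fell adjusted over the list alone). There nlp-3 (5.18 ± 1.09) and flp-8 (3.68 ± 1.04) led the rises, and nlp-31, nlp-33 and nlp-24 fell. Of 9 dopamine and serotonin neuron genes 5 rose (6 adjusted over the list alone). Among them were cat-4 (2.42 ± 0.418) and cat-1 (1.90 ± 0.461), the vesicular monoamine transporter. Camera gave adjusted p = 2.39e-16, 4.33e-07 and 0.000133 for these 3 lists, and adjusted p = 0.252, 0.332 and 0.252 with an estimated correlation. Motor neuron, glia and microRNA pathway lists were not called (camera adjusted p = 0.251, 0.748 and 0.726), with 0 of 21, 1 of 18 (daf-6, -1.42 ± 0.25) and 1 of 19 (vig-1, -0.87 ± 0.169) members past the threshold. The glia median of -0.0431 and mean of 0.0936 differ in sign. Touch receptor genes went both ways: mec-12 and alr-1 rose and mec-5, mec-2 and mec-7 were among 4 that fell, out of 17 (list median 0.2, mean -0.255, camera adjusted p = 0.478).

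Lists of other cell types were lower in mutant GFP+ cells. Of 58 body wall muscle genes 27 fell (37 fell and 4 rose adjusted over the list alone), with a median of -1.42. They included mup-2 (-3.99 ± 0.735) and tnt-3 (-3.54 ± 0.702), both troponin T, and clik-1 (-3.62 ± 0.731). Of 128 collagens 34 fell (45 adjusted over the list alone). Of 54 hypodermis genes 18 fell and 2 rose (29 and 4 adjusted over the list alone). The falls were led by the cuticle collagens dpy-14 (-4.29 ± 0.974) and dpy-17 (-3.87 ± 0.801), and dpy-8 rose (1.80 ± 0.195). Camera adjusted p was 3.96e-11, 4.66e-12 and 6.03e-08, and adjusted p = 0.266, 0.261 and 0.261 with an estimated correlation. Of 47 intestine genes 10 fell and 1 rose (16 and 1 adjusted over the list alone), and of 7 coelomocyte genes 4 fell (4 adjusted over the list alone), with cup-4 (-3.96 ± 0.864) and unc-122 (-3.33 ± 0.511). Camera gave adjusted p = 5.08e-07 and 0.00153, and adjusted p = 0.252 for both with an estimated correlation. In the pharynx list 0 of 28 genes passed (median -0.388, camera adjusted p = 0.0245; adjusted p = 0.518 with an estimated correlation).

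By camera with the preset correlation, the cell cycle, germline, ribosomal protein and oxidative phosphorylation lists were lower too, and the proteasome list was higher. Of 75 cell cycle genes 22 fell and 2 rose (38 and 2 adjusted over the list alone). Here mcm-7 (-3.47 ± 0.639), a replication helicase subunit, him-10 (-2.54 ± 0.566), a kinetochore protein, and scc-1 (-2.52 ± 0.511), a cohesin, fell, and orc-2 and rpa-1 rose. Of 45 germline genes 8 fell, including the P granule genes glh-1 (-2.23 ± 0.476) and deps-1 (-2.21 ± 0.491), and 3 rose, including pos-1 (2.29 ± 0.586). In this list 11 fell and 3 rose adjusted over the list alone. Ribosomal proteins had 4 of 75 members lower (2 adjusted over the list alone) and a median of -0.631. Oxidative phosphorylation had 1 of 42 lower, cox-17 (-1.04 ± 0.237), and the proteasome 1 of 33 higher, rpn-8 (0.52 ± 0.135), with 0 each adjusted over the list alone. Camera gave adjusted p = 1.1e-08, 0.0014, 9e-13, 1.33e-06 and 0.0145 for these 5 lists, and adjusted p = 0.261, 0.332, 0.332, 0.258 and 0.332 with an estimated correlation. Heat shock and stress genes were not called as a list (adjusted p = 0.0512), with ctl-2 and hsp-12.3 lower and ire-1 higher out of 43.

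The mutant count of 2730 moved with the arrays that set the shared spread. It was 6195 (3035 higher, 3160 lower) in the 10-array fit, which holds all 2730 in the same direction, 5163 with the 6 mutant arrays alone, and 4596 with the replicate block within strain. Leaving out mutant GFP+ replicate 1, 2 or 3 from the 12-array fit gave 1, 0 and 420 calls, and leaving out GFP- replicate 1 or 3 gave 444 and 21; in the 10-array fit every such count lay between 4604 and 6293. In that fit the cilium, sensory signalling and guanylyl cyclase lists also passed with an estimated correlation (camera adjusted p = 0.0461, 0.0236 and 0.0461). Members of lists with few or no calls above passed limma in it too. Among them were cha-1, unc-47, acr-12, snf-11 and unc-129 of motor neurons and che-12, vab-3, mls-2, che-14 and ptr-10 of glia. In the pharynx list tbx-2, cest-17, tnc-2 and myo-2 passed.

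GFP+ against GFP- in wild-type put the same question to cells that make the microRNA. With all 6 arrays the only call was F20D6.10, lower by 1.75 log2 units (log2 fold change -1.75 ± 0.171, limma adjusted p = 0.0215), while 2740 probe sets had an unadjusted p under 0.05 against 1127 expected. This call ended with the replicate number as a block (adjusted p = 0.0822, or 0.148 within strain). Without the 2 replicate 3 arrays, 1906 probe sets were higher and 1705 lower in GFP+ cells, 3611 in all, for 1503 and 1381 genes. Without the library labelled GFP- replicate 3 alone the count was 2705, and without GFP+ replicate 3 alone 394; leaving out any other wild-type array gave 0, or 1889 to 2164 in the 10-array fit. Leaving an array out of a pair makes a lone array, which is assumed to vary like the other groups. Without the pair, the rises were led by R102.2 (5.97 ± 0.255), F10E9.1 (5.65 ± 0.248), xbx-9 (5.64 ± 0.333) and nlp-3 (5.27 ± 0.269), and the falls by upb-1 (-4.87 ± 0.29), F35C12.3 (-4.67 ± 0.363), hsp-12.1 (-4.59 ± 0.447) and idhg-2 (-4.45 ± 0.477). With 12 arrays the same genes had smaller differences and larger errors, for example 4.05 ± 1.61 for R102.2 (adjusted p = 0.36) and -3.50 ± 0.716 for upb-1 (adjusted p = 0.248).

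The wild-type lists moved in the same directions as those of the mutant where both were called. In the 10-array fit 54 of 57 cilium genes rose in wild-type GFP+ cells (54 adjusted over the list alone; median 2.79), as did 32 of 46 sensory signalling genes, with 2 that fell (33 and 2 adjusted over the list alone), and 17 of 32 guanylyl cyclases (24 adjusted over the list alone). These passed camera with the preset correlation (adjusted p = 8.15e-46, 2.51e-18 and 2.6e-11) and the estimated one (adjusted p = 0.0393, 0.0173 and 0.0415 with an estimated correlation). Of 43 pan-neuronal genes 29 rose (34 adjusted over the list alone), and 43 of 58 body wall muscle genes fell while 2 rose (46 and 3 adjusted over the list alone), with adjusted p = 0.0978 and 0.196 with an estimated correlation. With all 12 arrays 0 list members passed and the cilium and muscle medians were 1.89 and -1.1 (camera adjusted p = 8.61e-20 and 1.09e-15; adjusted p = 0.34 and 0.333 with an estimated correlation); 2 of the 6 arrays carry the GFP+ profile and the wide 3' gap given above.

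**Figure D2:**
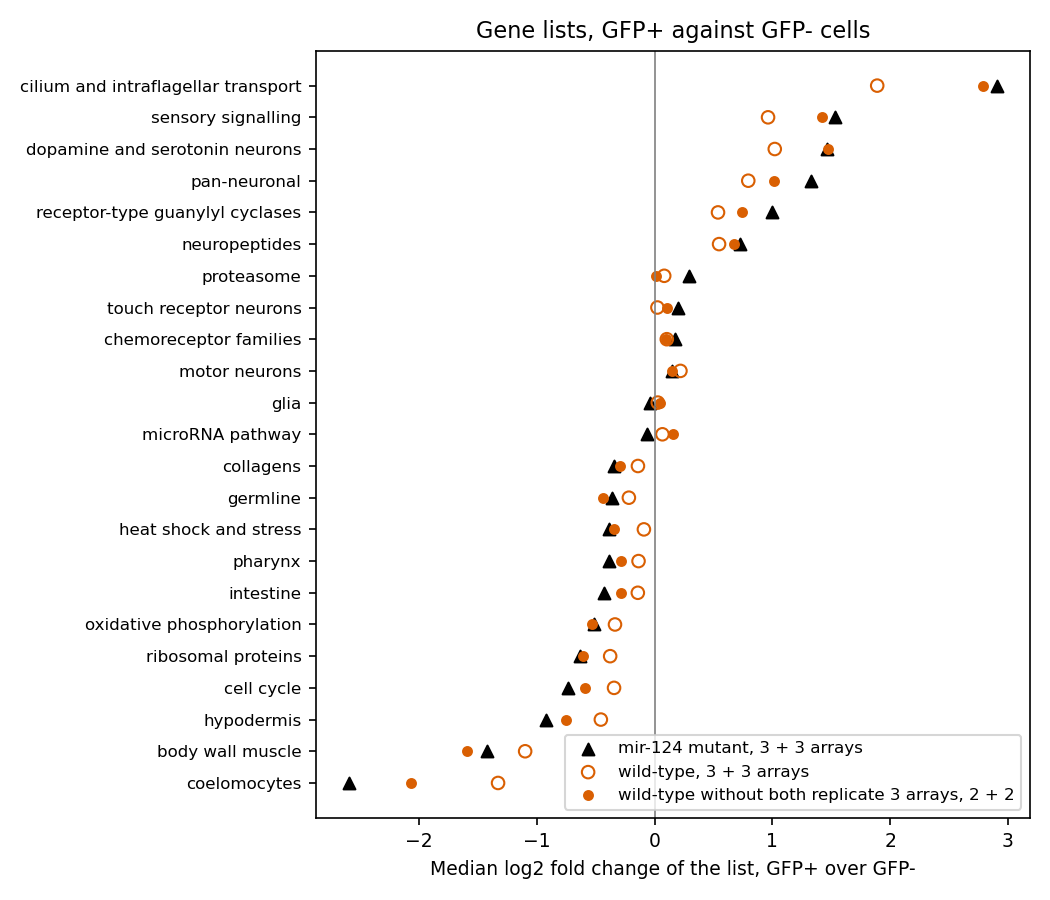
Median log2 fold change, GFP+ over GFP- (x axis), of each of the 23 gene lists (y axis) in the mutant (triangles), in wild-type with all arrays (open circles) and in wild-type without both replicate 3 arrays (filled circles). The cilium list lies at 2.91, 1.89 and 2.79, and the coelomocyte list at -2.6, -1.33 and -2.07.

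The GFP+ to GFP- fold changes of the 2 strains, which share no array, correlated at r = 0.926 across 17118 genes with 12 arrays and 0.956 with 10, with slopes of mutant on wild-type of 1.47 and 1.03. Genes are not independent replicates. In the 10-array fit 1439 genes were higher in both strains, against 214 for independent lists, 1305 were lower in both, against 202, and 0 were called in opposite directions.

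Mutant against wild-type in GFP+ cells asked what loss of the microRNA does where its promoter is active. At the locus, trpa-1 was at 9.55 ± 0.149 (SD, n = 3) in mutant and 7.39 ± 0.475 in wild-type GFP+ cells, with each mutant array above each wild-type array. The log2 difference of 2.16 ± 0.397 (SE) did not pass with 12 arrays (limma adjusted p = 0.834) and did without the wild-type replicate 3 arrays (1.89 ± 0.147, adjusted p = 0.00764). With 12 arrays 3 probe sets passed: rgs-5, a regulator of G protein signalling, rose (2.56 ± 0.295), F39E9.7, annotated as a pseudogene and read by an _x_at probe set, rose (2.19 ± 0.258), and ergo-1, an Argonaute read by an _s_at probe set, fell (-2.21 ± 0.244), each with limma adjusted p = 0.0427. With the replicate number as a block ergo-1 did not pass (adjusted p = 0.0714), and rgs-5 and F39E9.7 did (adjusted p = 0.0411 and 0.0175). In the 10-array fit 5 passed: trpa-1, tag-296 (1.44 ± 0.141), rgs-5 (2.2 ± 0.219) and ergo-1 (-2.39 ± 0.227), with limma adjusted p = 0.0163 for the last 3, and a probe set of several genes. F39E9.7 did not (adjusted p = 0.0968). The call of tag-296 depends on leaving out wild-type GFP+ replicate 3, which read 8.634. Wild-type GFP+ replicates 1 and 2 read 7.587 and 7.537, and mutant GFP+ cells 8.804 to 9.173.

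None of the 23 lists had a member past the limma threshold in GFP+ cells. There 233 probe sets had an unadjusted p under 0.05 with 12 arrays and 687 with 10, against 1127 expected. Both lie below the expected number, so the lack of calls does not show a lack of change. Without the replicate 3 pair 9 of 75 ribosomal protein genes rose adjusted over the list alone (median 0.445; camera adjusted p = 1.7e-46; adjusted p = 0.562 with an estimated correlation). Camera with the preset correlation called 12 lists with 12 arrays and 8 with 10, and 0 with an estimated correlation (smallest adjusted p = 0.405 and 0.284 with an estimated correlation). The proteasome list was higher in the mutant in both (medians 0.262 and 0.153). The neuropeptide list, called lower with 12 arrays (median -0.118, adjusted p = 0.0161), was not called with 10 (adjusted p = 0.742), where its median was -0.00719 and its mean 0.0426. The transgene marker genes lin-15A and lin-15B did not pass (0.04 ± 0.36 and 0.41 ± 0.358, limma adjusted p = 1 for both). The count of 3 was 0 with the 6 GFP+ arrays alone, 0 with each array shifted to one median, 1 after a further quantile normalization, and 0 when any of mutant GFP+ replicate 1, 2 or 3 or wild-type GFP+ replicate 1 or 2 was left out. From 10 arrays, leaving out mutant GFP+ replicate 1 or 3 gave 1 and 3 calls, and leaving out any other GFP+ array 0.

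Mutant against wild-type in GFP- cells gave the same comparison outside the reporter-positive cells. Here too trpa-1 was higher on every mutant array, at 7.786 to 8.072 against 5.419 to 7.089 in wild-type (n = 3 each). The log2 difference was 1.90 ± 0.397 with 12 arrays (limma adjusted p = 0.822) and 2.44 ± 0.147 with 10 (adjusted p = 0.000801). With 12 arrays 5 probe sets passed, each with limma adjusted p = 0.0226: rgs-5 (2.66 ± 0.295), F39E9.7 (2.27 ± 0.258) and F55C9.3 (2.91 ± 0.338) rose, as did a probe set that names no gene (3.74 ± 0.389), and ergo-1 fell (-2.19 ± 0.244). F55C9.3 read 3.33 to 3.507 in wild-type GFP- cells, below the lower quartiles of those arrays (4.102 to 4.218), so the size of its rise is uncertain. In the 10-array fit 4 passed: trpa-1, rgs-5 (2.68 ± 0.219, adjusted p = 0.00594), ergo-1 (-2.04 ± 0.227, adjusted p = 0.0416) and a probe set of several genes, while F39E9.7 and F55C9.3 did not (adjusted p = 0.0621 and 0.095). Across the 17118 genes the mutant to wild-type differences in GFP+ and GFP- cells correlated at r = 0.222 with 12 arrays and 0.464 with 10. Same-numbered GFP+ and GFP- arrays deviated together, so part or all of this could arise without a genotype effect.

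**Figure D3:**
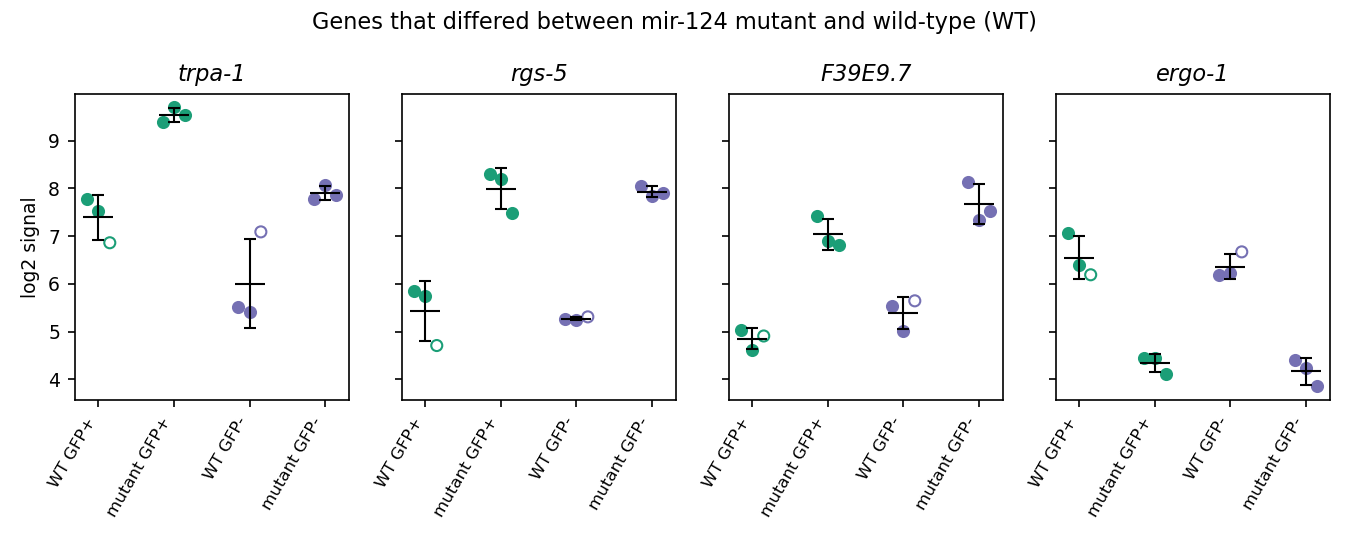
Log2 signal (y axis) of trpa-1, rgs-5, F39E9.7 and ergo-1 on each array, by group (x axis); points are arrays, bars are the mean ± SD of 3, and open points are the 2 wild-type replicate 3 arrays. In both fractions trpa-1, rgs-5 and F39E9.7 were higher and ergo-1 lower on each mutant array than on each wild-type array.

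The list results in GFP- cells turned on the library with the GFP+ profile. With 12 arrays the cilium list was lower in the mutant (median -0.966, camera adjusted p = 3.26e-09; adjusted p = 0.393 with an estimated correlation) and body wall muscle higher (median 0.361, adjusted p = 0.000244; adjusted p = 0.495 with an estimated correlation). Without both wild-type replicate 3 arrays the directions reversed, to 0.178 and -0.134 (adjusted p = 0.000965 and 0.0203; adjusted p = 0.643 and 0.84 with an estimated correlation). Ribosomal proteins were higher in mutant GFP- cells with 12 and 10 arrays (medians 0.349 and 0.456; adjusted p = 0.388 and 0.522 with an estimated correlation), with 0 of 75 members past the limma threshold (0 and 14 adjusted over the list alone). In GFP- cells 1130 probe sets had an unadjusted p under 0.05 with 12 arrays, against 1127 expected. The count of 5 was 1 with the 6 GFP- arrays alone, 9 with array weights, 1 without mutant GFP- replicate 2, and 2 without wild-type GFP- replicate 3. In that last fit 0 of the 5 were called in the same direction. The count was 0 when any of the other 4 GFP- arrays was left out. From 10 arrays it was 11 without mutant GFP- replicate 1, and 1 without wild-type GFP- replicate 1 or 2.

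The interaction asked whether loss of mir-124 changed genes differently in GFP+ and GFP- cells. No probe set passed: limma called 0 of 22548 with 12 arrays and 0 with 10, and 329 and 266 had an unadjusted p under 0.05 against 1127 expected. Neither fit paired the same-numbered GFP+ and GFP- arrays of a strain. For trpa-1 the difference of differences was 0.26 ± 0.561 with 12 arrays and -0.55 ± 0.208 with 10 (adjusted p = 1 in both). Leaving out mutant GFP- replicate 2 gave 1 call in either fit. With the preset correlation camera called 14 lists with 12 arrays and 8 with 10, and 0 with an estimated correlation (smallest adjusted p = 0.462 and 0.427 with an estimated correlation).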

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

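The tests of explanations in this part were chosen after the results they address had been seen, except the regroupings of the arrays other than the one that keeps pairs, and the fit without both wild-type replicate 3 arrays was added after seeing the data.

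Control probe sets, which the comparisons do not use, set both wild-type replicate 3 arrays apart, except GAPDH on the GFP+ array. The mean log2 signal of the hybridization controls was 10.55 on the GFP+ array and 10.13 on the GFP- array, against 8.583 to 9.404 on the other 10. The 3' minus middle difference of the polyadenylated controls was 4.221 and 4.061 against 1.665 to 2.313. The 3' minus 5' difference was 4.811 and 4.725 for actin, against 1.269 to 3.121, and 4.798 and 5.314 for ubiquitin, against 3.837 to 4.147. For GAPDH it was 2.839 on the GFP+ array, within the 1.806 to 3.376 of the other 10, and 3.95 on the GFP- array.

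The library labelled wild-type GFP- replicate 3 had the profile of GFP+ cells. A swap of the replicate 3 pair is argued against by the wild-type GFP+ replicate 3 library, whose cilium mean was 8.637, above the 5.726 of the highest other GFP- library. Poor RNA that flattened the contrast is argued against by its cilium minus muscle mean of 1.16, above the 0.524 to 0.85 of the other 5 GFP+ libraries. On 5163 probe sets called from the mutant arrays alone it lay 0.905 of the way from the other wild-type GFP- arrays to the GFP+ arrays, where wild-type GFP+ replicate 3 lay at 0.863 and the other GFP- arrays between -0.114 and 0.0503. A candidate explanation is that it was made from GFP+ cells, by a sorting or a labelling step that the sources used here do not record; no biological explanation was tested.

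Loss of mir-124 came with higher trpa-1 in both fractions. Release from the microRNA in the cells that express it was tested by whether the log2 rise in GFP+ cells was at least as large as in GFP- cells. The difference between the rises was 0.26 ± 0.561 with 12 arrays and -0.548 ± 0.208 without the wild-type replicate 3 arrays. Neither passed the limma threshold. Wild-type replicates 1 and 2 lay at 7.778 and 7.533 in GFP+ and at 5.509 and 5.419 in GFP- cells, so equal log2 rises are unequal amounts. Whether GFP- cells lack the microRNA was not measured here, so the difference decides nothing. A change at the mir-124 locus that acts on the host transcript or its probes in both fractions stays open: trpa-1 passed in both without that pair (larger adjusted p = 0.00764), but this restates the pattern and decides nothing. What the mutant allele removes was not used here.

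The genes rgs-5, F39E9.7 and ergo-1 differed between the strains in both fractions. Differences linked to the mir-124 region were looked for among the 200 measured genes nearest to mir-124 in gene order, with trpa-1 left out. There 0 of the 3 lie, which does not exclude linkage over a longer stretch. Of those 200 genes, 3 had an unadjusted p under 0.01 for the average genotype effect in the 10-array fit, against 338 of 16917 others (Fisher's exact test, one-sided, p = 0.764). The host gene trpa-1, not counted here, passed in that fit (limma adjusted p = 0.000104). Apart from trpa-1 no raised share near mir-124 was seen, which says nothing of rgs-5, F39E9.7 and ergo-1. As to normalization, the average effect counts same-numbered GFP+ and GFP- arrays as independent, although they deviated together. Its p-values may be too small and do not by themselves set normalization aside. A further quantile normalization or a shift to one median left the average effect of all 3 past the limma threshold (largest adjusted p = 0.00245). In GFP+ cells alone the call of rgs-5 ended, at adjusted p = 0.0667 and 0.0669, with a log2 fold change of 2.55 and 2.586 against 2.563 ± 0.295 before, and that of F39E9.7 at 0.0667 and 0.0684 with 2.18 and 2.212 against 2.189 ± 0.258, and at one median that of ergo-1 ended at 0.0669 with -2.193 against -2.215 ± 0.244; these adjusted p-values had been 0.0427, near the threshold, and the fold changes moved by less than their errors (the replicate block ended the GFP+ call of ergo-1, at 0.0714). Strain differences outside those 200 genes, linked to mir-124 or not, cross-hybridization of the _x_at and _s_at probe sets, and an effect of the microRNA stay open, as untested.

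By camera with a preset correlation, 14 lists differed between the fractions in their genotype effect with 12 arrays. The median difference was 1.02 for cilium, 0.698 for sensory signalling, 0.438 for guanylyl cyclases, 0.0885 for chemoreceptors, 0.461 for pan-neuronal genes and 0.15 for the proteasome. It was -0.364 for body wall muscle, -0.351 for intestine, -0.396 for hypodermis, -0.256 for collagens, -1.26 for coelomocytes, -0.399 for cell cycle, -0.239 for ribosomal proteins and -0.227 for oxidative phosphorylation. With an estimated correlation 0 lists passed (smallest adjusted p = 0.462). These medians rest in part on the library labelled wild-type GFP- replicate 3. Without it alone cilium was at -0.107 (adjusted p = 0.475), and body wall muscle was called in the opposite direction, at 0.2 (adjusted p = 0.00523). In the 10-array fit 8 lists were called. The medians for cilium, guanylyl cyclases, pan-neuronal genes, hypodermis, ribosomal proteins and oxidative phosphorylation were 0.0347, 0.124, 0.0711, -0.0585, -0.00451 and -0.0464, not called (adjusted p = 0.534, 0.17, 0.129, 0.0957, 0.5 and 0.192). Body wall muscle was called in the opposite direction, at 0.122 (adjusted p = 0.0421). Sensory signalling (0.165), chemoreceptors (0.0822), proteasome (0.125), intestine (-0.19), collagens (-0.0648), coelomocytes (-0.249) and cell cycle (-0.158) were called in the same direction as with 12 arrays, and 0 lists passed with an estimated correlation (smallest adjusted p = 0.427).

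Regrouping 3 arrays against 3 gives 10 splits, too few for a share under 0.05. The mutant GFP+ against GFP- count was 2730 with 0 as the highest of the other splits (1 of 10 as large), and 6195 with 0 in the 10-array fit. The wild-type count was 1 with 14 as the highest other (2 of 10 as large), from the split that exchanged the labels of the replicate 3 pair. Mutant against wild-type gave 3 and 5, with 0 as the highest other for GFP+ and GFP-. For called lists the real and highest other numbers were 16 and 16 in wild-type (2 of 10 as large), 18 and 18 in mutant (3 of 10), 12 and 11 for GFP+, and 18 and 17 for GFP-. For the interaction the real count was 0, which all 100 of 100 splits must reach, so they decide nothing. For the average genotype effect the real count was 5 and 2 of 100 splits were as large, but not all of these keep the pairs of same-numbered GFP+ and GFP- arrays. Only 10 splits keep the pairs, too few for a share under 0.05; the real count among them was 5 and the highest other 14 (2 of 10 as large). That split, also the highest of the 100, put all 4 replicate 3 arrays on one side with the wild-type replicate 2 pair. The split that put them with the mutant replicate 2 pair instead gave 0. A structure of the arrays by replicate number is therefore not settled by these counts.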

How the results depend on the processing

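The 10-array fit, array by array omissions from it, and its replicate block were chosen after seeing the data. The planned test of miR-124 seed sites was not run. Where a cause is not given the cause was not tested; fewer arrays also leave fewer degrees of freedom. Signal over background was not used here, and the number of arrays limits the precision.

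For wild-type GFP+ against GFP-, the count of 1 became 0 with the replicate block, with the block within strain and with only the arrays compared, 5130 with array weights and 3611 with 10 arrays. One array left out gave 0 to 2705, and 1889 to 2164 from 10 arrays. The mutant count of 2730 became 4596 with the block within strain (2554 in both), 5163 with only the arrays compared, 7127 with array weights and 6195 with 10 arrays; one array left out gave 0 (without mutant GFP+ replicate 2) to 2315, and 4604 to 6293 from 10 arrays. Trended eBayes, the dim filter, both scalings and the replicate block gave 2703 to 3327. For mutant against wild-type in GFP+, the count of 3 became 0 with only the arrays compared, 1 after quantile normalization, 0 at one median, 14 with array weights and 5 with 10 arrays; one array left out gave 0 to 2, and 0 to 3 from 10 arrays. In GFP-, the count of 5 became 1 with only the arrays compared and 9 with array weights. It was 0 to 2 with one array left out of 12, the 2 sharing 0 calls in the same direction with the 5. A mutant array left out of the 10 gave 3 to 11. The interaction count of 0 held in the alternatives run with all arrays, which did not include the block within strain. Without mutant GFP- replicate 2 the count was 1 from 12 and from 10 arrays. It was 0 without any other array from 12, and without any other mutant array from 10.

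With 10 arrays 7 list results reversed. Neuropeptides did so by camera direction only, with medians of -0.00719 in GFP+ and -0.0129 in GFP-. The others were the microRNA pathway in GFP+ (-0.000739), and in GFP- cilium (0.178), body wall muscle (-0.134) and pharynx (-0.0369). Body wall muscle also reversed in the interaction (0.122). One array left out reversed lists as well. Mutant against wild-type in GFP+, the medians ran from -0.112 to 0.0856 for collagens (highest without wild-type GFP+ replicate 3), -0.134 (without wild-type GFP+ replicate 2) to 0.445 for ribosomal proteins and -0.000739 to 0.255 for the microRNA pathway. In GFP- they ran from -1.51 to 0.178 for cilium, -0.444 to -0.0129 for neuropeptides, -0.134 to 0.784 for body wall muscle and -0.0369 to 0.408 for pharynx, the reversals without wild-type GFP- replicate 3. In the interaction they ran from -0.107 to 1.68 for cilium, -0.138 to 0.313 for neuropeptides and -0.802 to 0.2 for body wall muscle, reversed without that library, and -0.44 to 0.132 for ribosomal proteins, reversed without wild-type GFP+ replicate 3. Of 115 list results, 78 were called with the preset correlation, and all of these lost the call with an estimated one. The other 37 were called with neither. Their side of the threshold was kept by 113 of the 115 with the replicate block, 106 with quantile normalization and 111 with the mean of all probe sets of a gene. Of 241 named-gene results, 230 to 237 kept it under quantile normalization, one median, the dim filter (237 tested) and trended eBayes. With the replicate block 6 lost it and 13 gained it; with array weights 141 gained it, and with 10 arrays 143 gained and 3 lost it. One array left out ended the call in 414 of 1464 cases, 371 of them for GFP+ against GFP- in the mutant, and 107 gained it.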

Other observations

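These tests of gene families, grouped by symbol prefix, were chosen after the data had been seen. Each family with at least 10 measured members and under 50% of them in the fixed lists was tested with camera, and p-values are adjusted over these families.

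Further neuronal families were higher in GFP+ cells. Of 44 npr genes, which encode neuropeptide receptors, 13 rose in the mutant and 0 fell (median 0.636, adjusted p = 8.65e-09; adjusted p = 0.634 with an estimated correlation), and in the wild-type 10-array fit 19 rose and 0 fell (median 0.667, adjusted p = 9.27e-10; adjusted p = 0.423 with an estimated correlation). Of 30 glb genes, which encode globins, 13 rose and 1 fell in the mutant (median 0.921, adjusted p = 6.11e-06; adjusted p = 0.634 with an estimated correlation), and 15 rose and 1 fell in the wild-type 10-array fit (adjusted p = 0.465 with an estimated correlation).

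Families of secreted and extracellular proteins were lower in GFP+ cells of the mutant. Of 40 ttr genes, which encode transthyretin-like proteins, 15 fell in the mutant and 0 rose (median -0.806, adjusted p = 3.24e-06; adjusted p = 0.634 with an estimated correlation), and 14 fell and 1 rose in the wild-type 10-array fit (adjusted p = 0.215 with an estimated correlation). Of 12 lec genes, which encode galectins, 6 fell in the mutant and 0 rose (median -1.25, adjusted p = 0.00277; adjusted p = 0.634 with an estimated correlation). With all 12 arrays 0 members of these 4 families passed limma in wild-type, where 2740 probe sets had an unadjusted p under 0.05.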
